A study of Zea mays subsp. mays with 2 samples.

How the data were processed

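Polyadenylated RNA was sequenced from the shoots and the roots of maize seedlings of the inbred line B73, the source of the maize reference genome. The tissues were collected separately 14 days after germination. Strand-specific single-end libraries, 1 per tissue, were sequenced for 100 cycles, per the labels' protocols. The samples were grouped by their tissue label.

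The authors deposited 1 table of FPKM values, in which fragment numbers are divided by transcript length and by the mapped total of the library, with 1 column for shoots and 1 for roots. TopHat, a spliced aligner, and Cufflinks and Cuffdiff, which assemble transcripts and estimate their abundance, are named without versions in the submitters' processing notes. Their settings are not given in the sources used here. Each row is a transcribed locus with a Cufflinks-style identifier and a chromosome, strand, start and end on B73 RefGen_v2, per the file header. The table held 37398 loci on 10 chromosomes. The loci of the plus and minus strands carry separate prefixes and separate number series, and 11951 numbers occurred on both strands. Every listed locus had an FPKM above 1 in at least 1 library, with a lowest row maximum of 1.00 FPKM, so loci low in both tissues are outside the list. FPKM depends on the transcript length used, and for short loci it also depends strongly on the assumed fragment length.

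No locus carried a gene name, and 0 of the 37398 identifiers matched any of the 49888 genes of the maize RefSeq table at hand, which belongs to assembly Zm-B73-REFERENCE-NAM-5.0. Its coordinates were not used because the builds differ. The 29 gene lists fixed beforehand could therefore not be matched to loci, and neither they nor their percentiles among random lists are reported. Coding genes could likewise not be separated from noncoding RNAs, and exons and introns could not be told apart. Span means the genomic distance from the start to the end of a locus, introns included. No class of transcript could be formed, and loci were divided only by what the table gives, such as strand, span, level and position.

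The sequencing depth is unknown. Whether whole reads could be recovered was checked on low loci, since the locus length cancels in the ratio of the 2 libraries. Over all trial factors, the largest share of ratios within 0.01 on the log2 scale of a ratio of whole numbers up to 6 was 9.00% of 200 plus-strand loci and 10.1% of 257 minus-strand loci. Reads were not recovered, and no count test, counting interval or detection limit is given.

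For each locus the log2 ratio of roots over shoots was computed as log2((roots FPKM + 1)/(shoots FPKM + 1)), with a pseudocount of 1 FPKM. This scale understates the change of low loci. A locus was called higher in a tissue when the ratio was at least 4-fold and the FPKM at least 1 in that tissue, and detected at an FPKM of at least 1. With 1 library per tissue no test of the difference between tissues can be made, so no p-value, standard error or SD over replicates is given, and every difference is one between these 2 libraries. Of loci without names, the 2 with the largest positive and the 2 with the largest negative log2 ratio among those at 10 FPKM or more in the higher tissue were to be identified. Thresholds, the pseudocount and this rule were set before the data were examined. The span classes, the regions singled out, the locus groups, the runs and the counts in the ratio of deposited values were chosen after the values were seen.

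Same-strand loci separated by at most 1 kb were joined into locus groups, each represented by its most abundant locus. A run was a series of at least 4 locus groups that differed at least 4-fold in one direction with at most 100 kb between successive members. Runs were compared with 1000 shuffles of the log2 ratios among the groups of each chromosome. Rank correlations between neighbouring or overlapping loci are across loci, which are not independent replicates.

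Alternatives covered the pseudocount, the filter on low values, the scaling between tissues, the fold and detection thresholds, centring by strand, locus groups and short spans. The scripts were tested on simulated data with planted changes, which checks their arithmetic and direction only and says nothing about false calls between unreplicated libraries. Computations used Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.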

Results

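The series profiled polyadenylated RNA in the shoots and roots of 14-day-old B73 maize, with noncoding RNAs as its stated interest. There was 1 strand-specific library of each tissue. The 2 libraries were compared at 37398 transcribed loci, 18868 on the plus strand and 18530 on the minus strand. The loci spanned 101 to 537036 bp, with a median of 2443 bp. The sequencing depth of the libraries is unknown. The FPKM values summed to 1251263 in shoots and to 1184202 in roots, and the median locus stood at 8.91 FPKM in shoots and 8.20 FPKM in roots. There were no replicates, so none of the differences given here has a replicate check.

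Most listed loci were transcribed in both organs. At 1 FPKM or more, 34615 loci (92.6%) were detected in shoots, 33058 (88.4%) in roots and 30275 (81.0%) in both. A further 4340 loci (11.6%) reached this level in shoots and not in roots, and 2783 (7.44%) in roots and not in shoots. The shoot library listed 276 loci at 0 and the root library 597. Because the table holds only loci above 1 FPKM in at least 1 library, these shares describe the listed loci and not the genome.

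The organs differed most in a minority of loci, and shoot-biased loci were the more numerous. With 1 FPKM added to both levels, and no further scaling between the libraries, 2822 loci (7.55%) were at least 4-fold higher in shoots and 1476 (3.95%) at least 4-fold higher in roots. The other 33100 loci (88.5%) lay within 4-fold, and 26163 (70.0%) within 2-fold. On this scale at least 32-fold differences were found at 391 loci higher in shoots and 92 higher in roots, and at least 256-fold differences at 78 and 1. The added FPKM limits these ratios for loci near 0 in a tissue. In the ratio of the deposited FPKM values, leaving out loci at 0 in a tissue, 1035 loci were at least 32-fold higher in shoots and 352 in roots, and 287 and 48 were at least 256-fold higher, counts that were added after seeing the data. The median log2 ratio of roots over shoots was 0.06, with quartiles of -0.56 and 0.54. Spearman's rho between the libraries, across loci, was 0.74. The counts depended on the pseudocount: with 0.1 FPKM, 4751 loci were higher in shoots and 2707 in roots, and with 5 FPKM, 1348 and 592.

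**Figure D1:**
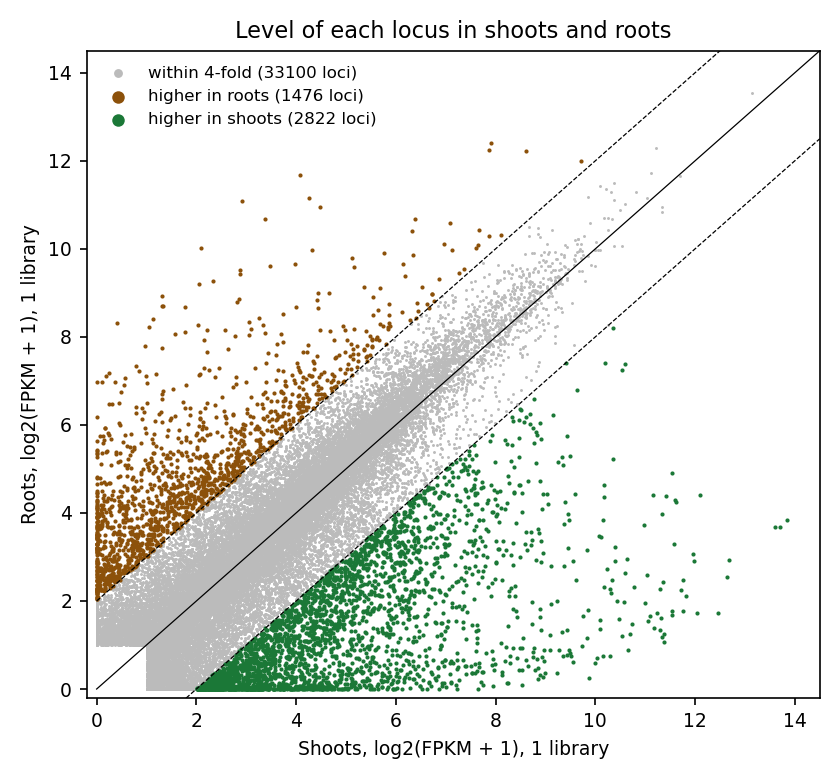
Level of each of the 37398 loci in shoots (x axis) and roots (y axis), both as log2(FPKM + 1) in 1 library; the solid line marks equal levels and the dashed lines mark 4-fold differences. The 2822 shoot-biased loci (green) reach higher levels and, on this scale, larger differences than the 1476 root-biased loci (brown).

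On the scale with 1 FPKM added, and among loci at 10 FPKM or more in the higher tissue, the largest shoot bias was that of M_XLOC_025549, on the minus strand of chromosome 8 from 70796779 to 70798941. It stood at 5603 FPKM in shoots and 2.32 FPKM in roots, a log2 ratio of -10.72. M_XLOC_007697, on the minus strand of chromosome 2 from 42257261 to 42259297, stood at 4195 FPKM in shoots and 2.33 FPKM in roots, a log2 ratio of -10.30. The largest root bias on this scale was that of M_XLOC_019146, on the minus strand of chromosome 5 from 191910165 to 191911369. Its levels were 2166 FPKM in roots and 6.50 FPKM in shoots, a log2 ratio of 8.18. M_XLOC_004588, on the minus strand of chromosome 10 from 1087065 to 1088682, was at 1042 FPKM in roots and 3.27 FPKM in shoots, a log2 ratio of 7.93. The file pairs none of these identifiers with a gene name, and what the annotation holds at these positions was not analysed here. The order depends on the added FPKM. Among loci at 10 FPKM or more in the higher tissue, 80 were at 0 in roots and 48 at 0 in shoots. The ratio of deposited values leaves these out. In the ratio of deposited values, among loci at 10 FPKM or more in the higher tissue and above 0 in the other, 13 loci exceeded the 2416-fold difference of M_XLOC_025549 and 24 exceeded the 334-fold difference of M_XLOC_019146.

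Most of the top loci of the shoots were far lower in the roots, while most of the top loci of the roots lay within 4-fold of their level in shoots. The 10 most abundant loci held 6.45% of the FPKM sum in shoots and 4.13% in roots, and the 100 most abundant held 19.5% and 13.7%. Of the 50 most abundant loci of shoots, 42 were at least 4-fold higher there than in roots. Of the 50 most abundant loci of roots, 16 were at least 4-fold higher there than in shoots, and 8 loci were among the top 50 of both. Among the 395 loci at 500 FPKM or more in a tissue, 113 (28.6%) were higher in shoots and 43 (10.9%) in roots. Among the 11321 loci whose higher level was at most 5 FPKM, these shares were 2.16% and 0.86%, on a scale whose pseudocount limits the ratio of low loci.

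The most abundant loci were identified by position after their values were seen. In shoots the highest was a minus-strand locus on chromosome 7 from 147057063 to 147058228, with 14761 FPKM against 13.4 FPKM in roots. It was followed by a pair on chromosome 1 that lay within a 32.8 kb stretch on opposite strands. The minus-strand member, from 247727655 to 247729365, had 13271 FPKM in shoots and 11.8 FPKM in roots. The plus-strand member, from 247758733 to 247760445, had 12525 FPKM in shoots and 11.9 FPKM in roots. The members spanned 1711 and 1713 bp, and whether reads were shared between them could not be checked without sequence. A single locus was among the 5 most abundant of both organs. It lies on the minus strand of chromosome 1 from 178476591 to 178478157 and had 9013 FPKM in shoots and 11878 FPKM in roots. The next most abundant in roots, on the plus strand of chromosome 2 from 127959950 to 127960704, had 5407 FPKM there and 239 FPKM in shoots.

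Some organ-biased loci lay side by side. On chromosome 3, 5 of 6 loci between 223353958 and 223531535, all on the plus strand, were higher in shoots. Of these, 4 loci of 780 to 1388 bp stood at 2306 to 3604 FPKM in shoots and 1.26 to 3.30 FPKM in roots, and the short locus next to the last of them at 366 FPKM and 0.07 FPKM. The sixth locus, between them, had 3.62 FPKM in shoots and 4.22 FPKM in roots. With loci at most 1 kb apart joined, the region held 5 locus groups, of which 4 were higher in shoots. On chromosome 7, 9 of 10 loci between 168791897 and 169033108 were higher in roots, 3 on the plus and 6 on the minus strand. They had 3.65 to 55.2 FPKM in roots and at most 0.64 FPKM in shoots, where 4 loci were listed at 0. The tenth locus had 22.2 FPKM in shoots and 26.3 FPKM in roots. On chromosome 9, a pair of plus-strand loci within 117172962 to 117178037 had 3289 and 412 FPKM in roots against 15.9 and 1.47 FPKM in shoots. The locus between them had 6.96 FPKM in roots and 14.2 FPKM in shoots. These regions were singled out after the values were seen, and reads shared between near-identical neighbouring copies could have been divided among them.

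**Figure D2:**
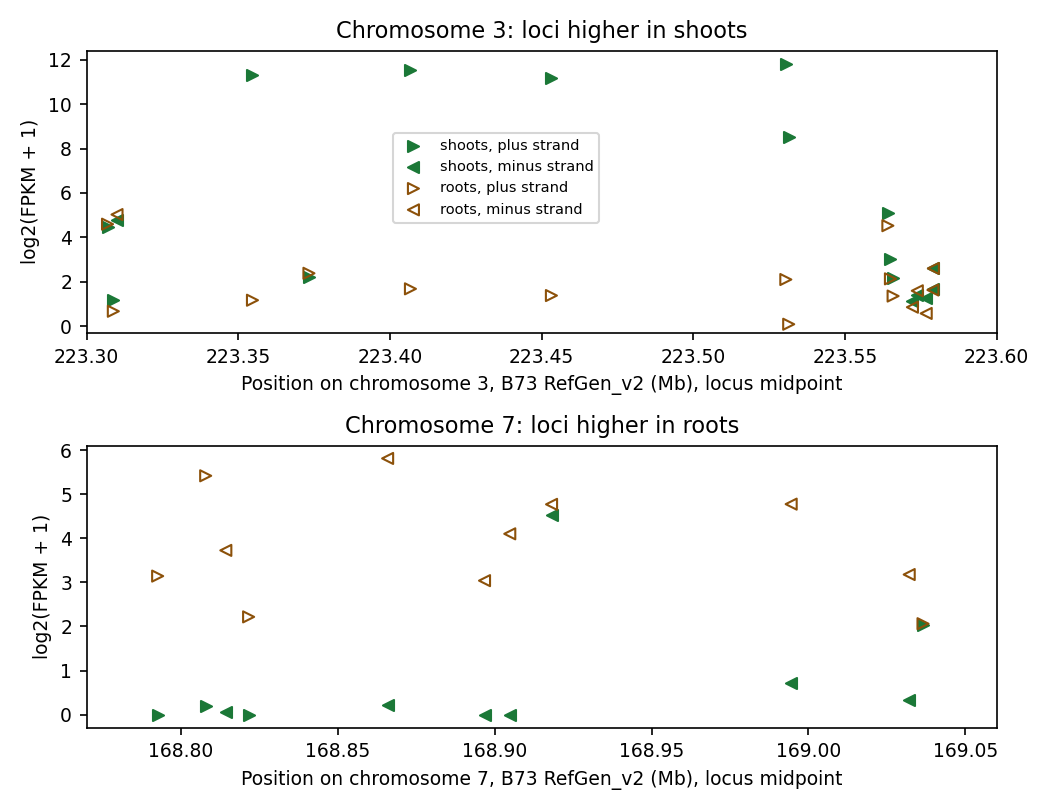
Loci by midpoint position (x axis, Mb, B73 RefGen_v2) and level (y axis, log2(FPKM + 1)) in shoots (filled green) and roots (open brown), with triangles pointing right for the plus strand and left for the minus strand. On chromosome 3 (upper panel) 5 of 6 neighbouring loci, or 4 of 5 locus groups, are higher in shoots than in roots. On chromosome 7 (lower panel) 9 of 10 are higher in roots than in shoots, at lower levels, while 1 locus within each region has similar levels in both.

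Across the genome, runs of root-biased locus groups were more frequent than in shuffled data. After same-strand loci within 1 kb were joined, 31003 locus groups remained. They formed 9 runs of at least 4 root-biased groups, against a mean of 1.13 and a maximum of 6 runs in 1000 shuffles. The longest was that on chromosome 7, with 9 groups, and the longest in any shuffle held 7. The next longest, on chromosome 4 from 28615664 to 28746449, held 6 root-biased groups among 9, at 48.5 to 173 FPKM in roots and 10.4 to 37.0 FPKM in shoots. A run on chromosome 2, from 24813747 to 24875004, held 4 groups, all on the minus strand, at 104 to 406 FPKM in roots and 9.06 to 30.6 FPKM in shoots. Shoot-biased groups formed 18 runs, against a mean of 11.1 and a maximum of 21 in the shuffles, of which 27 held at least as many. The longest shoot run held 6 groups, and the longest in the shuffles held 10. With 200 kb allowed between members there were 21 root runs and 49 shoot runs, and with 50 kb there were 7 and 5. None of the 1000 shuffles held as many root runs at either distance, while 351 held as many shoot runs at 200 kb and 96 at 50 kb. The shuffles treat locus groups as independent, while same-strand neighbours at gaps of 5 to 20 kb had a rank correlation of 0.25. An excess over the shuffles can therefore arise from the likeness of near neighbours alone. The definition of a run was chosen after the values were seen.

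Every chromosome carried more shoot-biased than root-biased loci. The share of loci at least 4-fold higher in shoots ranged from 6.22% on chromosome 8 to 8.06% on chromosome 2. The share higher in roots ranged from 3.27% on chromosome 8 to 4.82% on chromosome 10. Between the strands, 7.69% of plus-strand and 7.40% of minus-strand loci were higher in shoots, and 3.91% and 3.98% were higher in roots. The median log2 ratio was 0.01 on the plus strand and 0.10 on the minus strand.

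The share of loci called organ-biased differed among classes of genomic span. Among the 1926 loci spanning 101 to 200 bp, 9.87% were higher in shoots and 8.72% in roots. Among the 8939 loci spanning over 5000 bp, these shares were 5.39% and 1.31%. The shares did not fall steadily with span. The 4343 loci of 201 to 500 bp had 5.13% higher in shoots and 2.14% higher in roots. Loci of 501 to 2000 bp had 9.68% higher in shoots and 6.78% higher in roots, and those of 2001 to 5000 bp had 7.85% and 3.43%. The median level in shoots was 8.55 FPKM for the shortest class, 2.61 FPKM for 201 to 500 bp and 16.9 FPKM for the longest. The span classes also differ in level, in the same libraries, and FPKM of the shortest loci depends most on the assumed fragment length. The 1 FPKM added to both levels keeps the lowest loci from being called. The 201 to 500 bp class had the lowest medians, 2.61 FPKM in shoots and 2.06 FPKM in roots. With a pseudocount of 0.1 FPKM the share called in either direction rose from 18.6% to 26.9% at 101 to 200 bp. Above 5000 bp it rose from 6.70% to 8.80%. At a given FPKM a shorter transcript yields fewer fragments, and with the depth unknown counting error was not assessed.

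**Figure D3:**
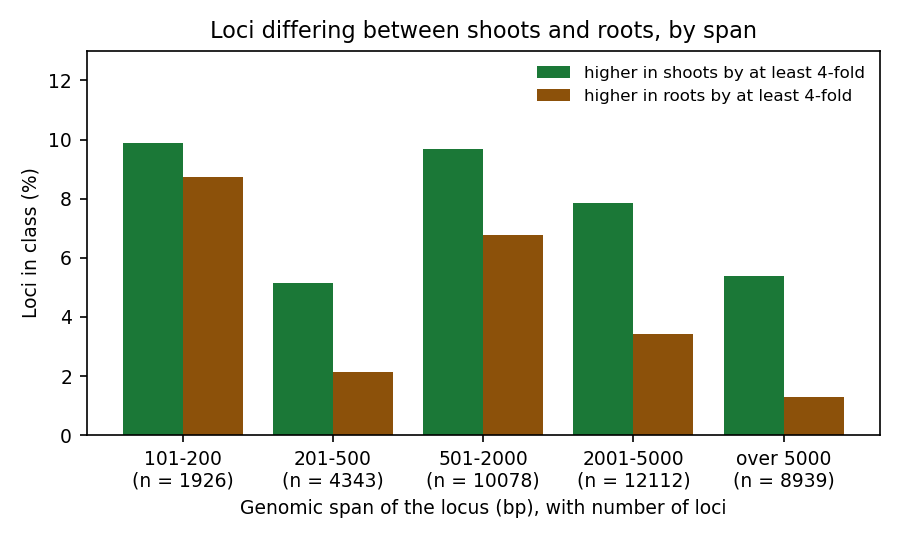
Share of loci (y axis, percent of the class) at least 4-fold higher in shoots (green) or in roots (brown) in 5 classes of genomic span (x axis, bp; n is the number of loci), in 1 library per tissue. The root-biased share is 8.72% at 101 to 200 bp, 2.14% at 201 to 500 bp and 1.31% above 5000 bp. The 1 FPKM added to both levels limits calls at low loci, and the class of 201 to 500 bp has the lowest median level.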

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

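Of the counts of detected and of organ-biased loci, 24 values under other settings stayed within 1.5 times those reported and 9 did not. A detection level of 5 FPKM left 19865 loci detected in both tissues. At least 4-fold differences numbered 2707 in roots and 4751 in shoots with a pseudocount of 0.1 FPKM, and 592 and 1348 with 5 FPKM. At least 2-fold differences numbered 4834 and 6401, and at least 8-fold differences 549 and 1394. These counts move by construction, with the threshold or with the shrinkage of low loci. Shoot-biased loci outnumbered root-biased ones in each of these settings and in the 3 scalings and 3 settings added after seeing the data (centring each strand, joining loci within 1 kb, dropping spans under 200 bp). Other scalings shifted all log2 ratios by at most 0.07. Removing the filter on low values changed nothing, because every listed locus already exceeds 1 FPKM. Of the other values, 28 stayed close and 14 moved, with no change of sign in a log2 ratio or correlation. Close means within 1.5 times for the fold differences of named loci and the numbers of runs. For percentages and correlations it means within the 95% sampling interval of the main value, and for the strand offset within 1 SD over chromosomes. That interval takes loci and pairs as independent, which they are not, and it narrows as their number grows. By this rule the opposite-strand correlation of neighbours within 1 kb stayed close at 0.024 against 0.075, with both loci at 5 FPKM or more. The same-strand one moved at 0.66 against 0.63, with a pseudocount of 0.1 FPKM. The counts of 28 and 14 are therefore no measure of stability. The order of the tissues in the number of runs did change: shoot runs outnumbered root runs at 100 and 200 kb between members, and root runs outnumbered shoot runs at 50 kb, with 7 against 5, distances chosen after seeing the data. Other settings for the gene lists were not run, since no locus could be matched to a gene. No paired analysis was possible because each tissue has 1 library, and for the same reason no library could be left out. The unknown depth limits what can be said of low loci.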

Other observations

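Rank correlations of neighbouring and of overlapping transcripts were planned before the data were examined, for pairs that include an annotated gene. No locus carried a gene name, so they were computed between unnamed loci instead. Their division by strand and by gap was not set beforehand. The classes by locus density, the filters at 5 FPKM, the shuffles and the tests of explanations were chosen after the patterns were seen. Shoot bias was more common in locus-poor parts of the chromosomes. Windows of 5 Mb were divided by their number of locus groups into 3 classes holding similar numbers of groups. In the class with 1 to 73 groups per window, 9.86% of 10698 groups were at least 4-fold higher in shoots, against 7.17% of 10330 groups in the class with 108 to 230 groups per window. The sparse share was the larger on 10 of 10 chromosomes. Root bias showed no such difference between these classes, with 3.99% and 4.03%, and its sparse share was the larger on 5 of 10 chromosomes. In the middle class, with 74 to 106 groups per window, 7.65% of 9975 groups were shoot-biased and 4.73% root-biased. When the groups were divided into 4 classes by level, the shoot-biased shares of sparse and dense windows were 11.8% and 5.94% from 4.96 to 14.9 FPKM, and 14.4% and 13.1% above 38.4 FPKM.

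Loci listed on opposite strands overlapped in 1983 pairs, made up of 3577 loci, with a median overlap of 406 bp. How completely the libraries kept the strands apart was not measured. In 880 pairs 1 locus lay wholly inside the other. The more abundant locus of a pair was the one with the larger sum over both tissues. In the tissue where that locus was higher, its partner stood at a median of 15.3% of its level, with a 10th percentile of 1.33%. The log2 ratios of the partners had a rank correlation of 0.12 across pairs, and of 0.076 where both were at 5 FPKM or more in a tissue. Both partners were shoot-biased in 18 pairs and root-biased in 4, and in 2 pairs the partners had opposite bias. The 22 pairs with the same bias compare with a mean of 13.9 and a maximum of 26 when partners were shuffled 1000 times. The number lies above the mean and under the maximum. How many shuffles reached 22 was not counted, so an excess is neither shown nor excluded. On chromosome 2, a plus-strand locus from 6473777 to 6482852 had 26.1 FPKM in shoots and 1.74 FPKM in roots. The minus-strand locus from 6475924 to 6486253, which overlaps it by 6929 bp, had 17.2 FPKM in shoots and 102 FPKM in roots. The other pair with opposite bias lies on chromosome 3. Its plus-strand locus, from 58078414 to 58081645, had 3.46 FPKM in shoots and 30.0 FPKM in roots, and its minus-strand locus, from 58081466 to 58084089, had 103 FPKM in shoots and 11.4 FPKM in roots.

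The median log2 ratio of roots over shoots was 0.087 higher on the minus than on the plus strand. It was higher on 10 of 10 chromosomes, by 0.06 to 0.13, while swapping the strands at random in 1 Mb blocks 1000 times gave at most 0.03. The 1% most abundant loci took 31.8% of the shoot sum on the minus strand and 28.4% on the plus strand, but they also took more of the root sum there, 24.9% against 19.5%. If each strand were scaled by its own sum, these shares would predict an offset of -0.030, opposite to that seen. The sums were not equal, however, with 628635 in shoots and 574380 in roots on the plus strand. On the minus strand they were 622628 and 609822. FPKM is scaled by mapped totals, which these sums do not give, so the prediction cannot decide whether abundant loci caused the offset. A candidate explanation is that the strands were quantified and scaled separately, as their separate number series would allow: without a pseudocount the offset stayed between 0.073 and 0.118 in 5 classes of level. No biological explanation was tested.

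Same-strand neighbours were much more alike than opposite-strand neighbours. The rank correlation of their log2 ratios was 0.63 at gaps of 1 to 1000 bp, across 3792 pairs. Opposite-strand neighbours at these gaps had 0.075 across 1360 pairs. Where both loci were at 5 FPKM or more in a tissue these values were 0.52 and 0.024. The difference between them argues against regulation of the whole region, on both strands, as the cause. Among same-strand pairs the rank correlation was 0.74 at 1 to 200 bp and 0.27 at 1 to 5 kb, which is consistent with parts of 1 transcript being listed as separate loci. Same-strand pairs at 5 to 20 kb still had 0.25, against 0.10 on opposite strands, and copies in tandem remain open there, untested without sequence. Joining loci within 1 kb left 31003 groups, of which 2559 were shoot-biased and 1315 root-biased.

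The most shoot-biased loci among those at 1000 FPKM or more in shoots kept a small signal in the root library. At lower levels this did not always hold: 80 loci at 10 FPKM or more in shoots were at 0 in roots. Of 98 loci at 1000 FPKM or more in shoots, 45 were at least 256-fold lower in roots, with 1 FPKM added to both levels. There they stood at 0.041% to 0.308% of the shoot level, with a median of 0.092%. Choosing loci at least 256-fold lower in roots caps these percentages, so their upper end and median partly reflect that choice. Shoot material or reads carried into the root library at one rate would give one percentage, but the 90th percentile was 4.28 times the 10th, which argues against it as the whole of that signal, as far as can be said with the depth unknown. The root levels of these loci rose with their shoot levels, with a Spearman's rho of 0.62, as carry-over would give, although choosing loci by their ratio also favours this. As a part of that signal carry-over cannot be told apart from low transcription in roots: none of the 247 loci at 500 FPKM or more in shoots was at 0 in roots, and the lowest percentage among them was 0.021%. Of the 2024 loci at 100 FPKM or more in shoots, 3 were at 0 in roots and the lowest percentage above 0 was 0.017%, at root levels that cannot be weighed without the depth. Of 263 loci at 500 FPKM or more in roots, the lowest shoot level was 0.30% of the root level.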
